A study of Homo sapiens with 4 samples.

How the data were processed

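Small RNA libraries (TruSeq small RNA chemistry) were made from exosomes purified by differential ultracentrifugation of conditioned medium. Parental cells of the lines HCT15 and HCT29 were grown in complete RPMI and their exosomes collected in exosome-depleted complete RPMI, per the labels, and spheres were grown for 3 weeks in defined medium with 10 ng/ml bFGF and 10 ng/ml EGF. The growth protocol text of the HCT29 samples names HCT15, and the deposited sheets of HCT15 sphere and HCT29 parental are named HT15 and HT29. The lines are called HCT15 and HCT29 here as in the sample titles, and which line the HCT29 libraries come from is not settled by the labels. There are 4 libraries, 1 per line and culture, and no column was left out.

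The authors' values are RPM, reads scaled to a common library total, for 2588 mature miRNAs in each library, per the file headers of both HCT15 tables. The headers of both HCT29 tables name the culture and no unit. Their deposited values were read as RPM because they are whole multiples of 1 step and sum to less than the scaling total, as in HCT15. The submitters' processing notes name hg19 as the genome build, and the aligner version and the annotation release are not given in the sources used here. No raw counts were used: reads were recovered by dividing each value by the smallest step of its library, and 100% of the nonzero values were whole within a tolerance of 0.1 read. The implied totals are 146648, 461226, 110666 and 530920 reads for HCT15 parental, HCT15 sphere, HCT29 parental and HCT29 sphere, and the listed miRNAs hold 77.8, 89.9, 87.3 and 86.8% of them. 1 read is 6.82, 2.17, 9.04 and 1.88 RPM in the same order, and sphere libraries were 3.15 times (HCT15) and 4.80 times (HCT29) as deep as parental ones. Recovered reads served for intervals, floors and alternatives.

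Within each line, the log2 ratio of RPM + 1 (sphere over parental) was taken for miRNAs with at least 10 reads in a library compared, and called higher or lower at 2-fold or more. The plan had put TMM-scaled counts first and this form second, for values that are not counts. The second form was made the main one because the deposited values are RPM. Since whole reads could be recovered, TMM scaling was also possible and is given as an alternative. Fold changes in the text are ratios of RPM without the added 1, each with an exact conditional binomial (Clopper-Pearson) 95% interval on the recovered reads. Against a count of 0, a fold marked at least is computed with 3 reads in that library. That floor lies below the exact 95% upper limit of a count of 0 (in HCT15 parental 20.5 against 25.2 RPM) and leaves out the counting error of the other count. Exact lower limits are smaller, such as 179 rather than 221 for miR-371a-5p between the parental libraries. Against 1 to 3 reads the ratio is given with its interval. Overlap between the lines is given beside the number that independent lists would share, and the correlation across miRNAs has a bootstrap interval from 2000 draws. The test over all 4 libraries was limma with a mean-variance trend on log2(RPM + 1), with terms for line and culture, on 222 miRNAs with at least 10 reads in at least 2 libraries. It has 1 residual degree of freedom, so the spread is in effect pooled over miRNAs, and Benjamini-Hochberg adjusted p under 0.05 is the threshold. It treats the pair of lines as replicates of the culture effect, and the parental and sphere libraries of a line as replicates of the line effect.

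Before the data were examined, 30 miRNA lists were fixed: the let-7, miR-17-92, miR-200, miR-34, miR-15 and miR-16, miR-29, miR-30, miR-125 with miR-99 and miR-100, miR-10, miR-181, miR-148 and miR-152, miR-146, miR-320, miR-378, miR-183-96-182, miR-221 and miR-222 and miR-23-27-24 families and clusters, hypoxia (miR-210), intestinal epithelium, colorectal cancer-raised, pluripotent stem cell, the DLK1-DIO3 and chromosome 19 clusters, markers of blood cells, serum carry-over, fibroblasts and smooth muscle, muscle, nerve and endothelium, and entries overlapping other abundant RNAs. Some lists share members, such as miR-451a and miR-486 in the blood and serum lists. For each, the median log2 ratio was placed among 10000 random lists of the same size matched on abundance. The rule for named miRNAs, also fixed before, took per line the 10 highest and 10 lowest called ratios among miRNAs with at least 50 RPM in a library, the 5 most abundant of each library, up to 10 each way past limma for culture (0 passed), the 8 each way with the largest smaller ratio of both lines, up to 4 members per list, and always miR-146a-5p and miR-21-5p, which gave 125 miRNAs. Named outside the rule, after their values were seen, are miR-122-5p, miR-143-3p, miR-145-5p, miR-33b-5p, miR-30a-5p, miR-1290 and some of the miRNAs past limma between the lines (miR-127-3p, miR-136-3p, miR-155-5p, miR-194-5p, miR-409-3p, miR-410-3p and miR-411-5p).

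Hairpin positions and host genes were read from GENCODE v29 (GRCh38) by hairpin name and were not mixed with the authors' hg19 mapping. miRNAs that share mature sequence or nearly so cannot be assigned to a hairpin: miR-199a-3p and miR-199b-3p have identical values in every library. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

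Alternatives fixed before were TMM and DESeq2 scaling, totals of listed reads, totals without the 5 most abundant miRNAs, no filter and a filter of 100 reads, pseudocounts of 0.1 and 10, prior counts of 0.5 and 5 reads, a 4-fold threshold, and edgeR, DESeq2, limma voom and fits with the other term left out. The interval as a criterion was in the plan's first form and in its count of miRNAs shifted alike in both lines. Its use with RPM + 1 within a line was chosen after seeing the data. Also chosen after seeing the data were thinning of sphere reads to the parental total, limma on TMM-scaled values, edgeR with the deposited totals, leaving out each library with the other term left out, leaving out the chromosome 19, DLK1-DIO3 and fibroblast lists, and counting miR-199a-3p and miR-199b-3p once in the fibroblast list. limma was tested on simulated data with the same 222 miRNAs and 60 changed ones, 20 each at 4-fold, 16-fold and 64-fold: at a dispersion of 0.05 it recovered 17, 20 and 20 with 4 false calls among 162 unchanged, and at 0.3 it recovered 8, 19 and 20 with 3 false calls. In the same simulations edgeR gave 5 and 3 false calls and DESeq2 gave 2 and 7, at dispersions of 0.05 and 0.3. The simulations gave both lines the same culture effect. In the real libraries the ratios differed between the lines (SE 1.29 for miR-146a-5p by limma), so these recoveries do not show the power of the real fit. Reads that matched no listed miRNA and the raw sequences were not analysed here.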

Results

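Exosomes are small vesicles that cells release into their medium, and their miRNAs were sequenced here from cultures of a pair of human colon cancer cell lines, labelled HCT15 and HCT29. Each line was grown as parental cells in complete RPMI, with exosomes collected in an exosome-depleted form of that medium, and as spheres, floating colonies grown in defined stem cell medium and used to enrich for cells with stem-like properties. The study set out to find miRNAs that matter for the malignant behaviour of cancer stem cells. Each of the 4 groups holds 1 library, so no ratio within a line has a replicate error or a p-value. The values are RPM (reads scaled to a common library total), and every nonzero value converts to whole reads within 0.1 read. The library totals implied by that conversion are 146648 reads for HCT15 parental, 461226 for HCT15 sphere, 110666 for HCT29 parental and 530920 for HCT29 sphere. Of 2588 listed miRNAs, 476, 712, 392 and 423 had at least 1 read in those libraries, in that order. Taking 3 reads as the floor, a count of 0 is placed at 20.5 RPM in HCT15 parental, 6.50 in HCT15 sphere, 27.1 in HCT29 parental and 5.65 in HCT29 sphere. Exact 95% upper limits of a count of 0 are higher, such as 25.2 RPM in HCT15 parental and 33.3 in HCT29 parental. Intervals are exact 95% Clopper-Pearson intervals, and like the floors they cover counting error only.

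A few miRNAs made up most of the miRNA reads of each library, and shares here are of all listed miRNA reads. miR-10a-5p, which lies among the HOXB genes, was the most abundant miRNA in all 4 libraries, with 28.8% of the listed miRNA reads in HCT15 parental (28.5 to 29.1), 48.0% in HCT15 sphere (47.9 to 48.2), 24.3% in HCT29 parental (24.0 to 24.6) and 23.5% in HCT29 sphere (23.3 to 23.6). miR-192-5p, a miRNA of intestinal epithelium, took 7.82% and 8.67% of the HCT29 parental and sphere reads, against 0.145% and 0.513% in HCT15. miR-99b-5p took 14.1% and 12.7% in HCT29 and 1.43% and 1.21% in HCT15. miR-21-5p, widely raised in tumours, took 2.93% and 3.49% in HCT15 parental and sphere and 6.06% and 1.51% in HCT29. The 5 most abundant miRNAs of a library held 56.3% in HCT15 parental, 61.9% in HCT15 sphere, 59.4% in HCT29 parental and 62.3% in HCT29 sphere. The hairpin of miR-10a lies on chromosome 17 (GRCh38) from 48579838 to 48579947, in an intron of HOXB3, and that of miR-21 lies on the same chromosome from 59841266 to 59841337, in an exon of VMP1.

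**Figure D1:**
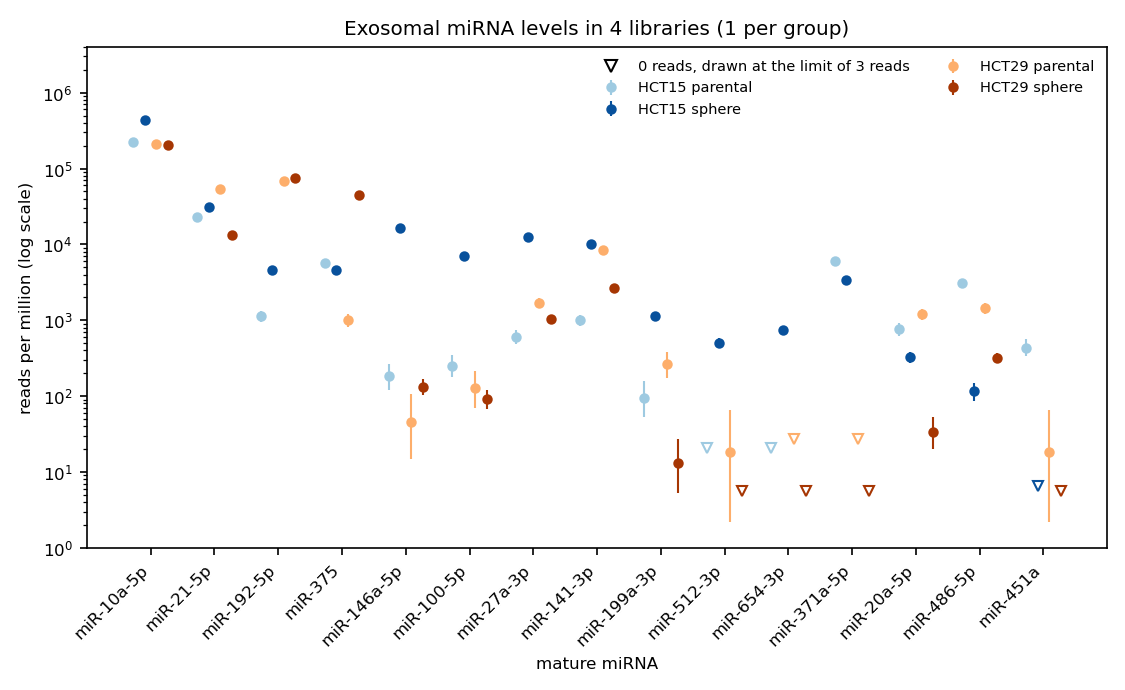
Abundance of selected miRNAs in the 4 libraries, in RPM on a log axis, each point 1 library with its 95% counting interval and open triangles marking a count of 0, drawn at the floor of 3 reads. miR-10a-5p is the highest point in every library, miR-146a-5p goes from 184 to 16215.5 RPM in HCT15, and miR-375 goes from 994 to 45016 RPM in HCT29.

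HCT15 sphere exosomes were compared with HCT15 parental exosomes to ask which miRNAs differ when the line grows as spheres. The sphere exosomes carried far more miR-146a-5p, a miRNA induced by NF-kB that represses the signalling proteins TRAF6 and IRAK1: 16215.5 RPM against 184, which is 88.1-fold higher (60.5 to 134). They also carried more of miR-100-5p (28.2-fold, 20.4 to 40.1) and miR-125b-5p (8.33-fold, 5.59 to 13.0), which are made from the long noncoding host gene MIR100HG, although miR-125b-5p has a further copy elsewhere. Several miRNAs of blood and nerve cells were lower, led by miR-9-5p with 191 parental reads and 1 sphere read (601-fold, 107 to 2.38e+04) and by miR-451a, an erythroid miRNA, with 64 parental reads and 0 sphere reads, at least 67.1-fold lower. The most abundant let-7 member, the tumour suppressor let-7a-5p, was 5.34-fold lower (5.13 to 5.56).

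The miR-146 list had both measured members higher, with miR-146b-5p 6.84-fold higher (4.96 to 9.69). In the miR-23-27-24 clusters, 4 of 7 measured members were at least 2-fold higher and 2 lower (1 under TMM scaling). Among the higher ones, miR-27a-3p was 20.4-fold higher (16.6 to 25.5), miR-24-3p 13.6-fold (9.97 to 19) and miR-23a-3p 3.48-fold (2.94 to 4.14). Hairpins of these 3 lie within 1 transcript on chromosome 19, that of miR-27a from 13836440 to 13836517, although miR-24-3p has a further copy on chromosome 9. The miR-125, miR-99 and miR-100 list had 4 of 8 members higher and 1 lower (0 under TMM). The p53-linked miR-34 list had 3 of 3 higher, 2 of them with intervals that exclude 1, and miR-34a-5p was 6.04-fold higher (2.26 to 22.7) on 4 parental reads. In the miR-320 list 3 of 4 were higher, miR-320d 6.36-fold, while miR-320a had a ratio of 0.650 and the summed RPM of the list was 1.10 times the parental value (1.02 to 1.19). Of the 5 measured miRNAs of intestinal epithelium 2 were higher (3 under TMM), miR-192-5p 4.10-fold (3.50 to 4.83) and miR-215-5p 3.66-fold (1.34 to 14.0), with the summed RPM at 1.20 times the parental value (1.13 to 1.28). In the miR-183-96-182 cluster, which is raised in colorectal tumours, 2 of 4 were higher, miR-183-5p by 4.61-fold (4.06 to 5.26), but the summed RPM was 0.966 times the parental value (0.932 to 1.00).

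In the miR-17-92 clusters, which promote proliferation, 10 of 15 members were at least 2-fold lower in HCT15 spheres and 0 higher, with a median log2 ratio of -1.27, but TMM scaling left 4 lower (median -0.66) and DESeq2 size factors 5 (-0.74). Their most abundant member, miR-92a-3p, was 3.02-fold lower (2.95 to 3.10), with a log2 ratio of -1.60 that became -0.99, within 2-fold, under TMM and -1.07 under DESeq2 factors. The let-7 list had 6 of 16 lower and 1 higher, with 4 lower and 2 higher under either scaling, and the miR-30 list had 6 of 9 lower and 2 higher, with 3 lower under TMM and 4 under DESeq2 factors. None of the higher members of these lists had an interval that excludes 1. The miR-200 family, which maintains the epithelial state, split: miR-141-3p was 10.1-fold higher (8.55 to 12.0) and miR-200a-3p 3.82-fold higher (2.81 to 5.32), while 4 of the other members (3 under TMM) were lower, among them miR-200b-5p (5.50-fold, 2.15 to 15.1). The summed RPM of this family was 1.59 times the parental value (1.5 to 1.69).

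Clustered and stromal miRNAs were also higher in the HCT15 sphere library. In the chromosome 19 cluster, a primate-specific group active in placenta and in stem cells, 14 of 15 members were higher, 8 of them with intervals that exclude 1. The summed reads of the list were 7 in the parental and 655 in the sphere library (29.8-fold in RPM, 14.4 to 74.3). With 7 parental reads over the whole list, all 15 members passed the filter of 10 reads through the sphere library alone. The filter therefore favoured higher calls in this list. Its most abundant member, miR-512-3p, had 0 and 233 reads, at least 24.7-fold higher. In the imprinted DLK1-DIO3 cluster on chromosome 14, 19 of 23 were higher, 10 of them with intervals that exclude 1, with summed reads of 213 and 2105 (3.14-fold in RPM, 2.73 to 3.63), and miR-654-3p had 0 and 339 reads, at least 35.9-fold higher. The fibroblast and smooth muscle markers were higher too, 7 of 7, or 6 of 6 with miR-199a-3p and miR-199b-3p, which have identical values, counted once. Among them were miR-199a-5p with 0 and 176 reads, at least 18.7-fold, and miR-199a-3p at 11.8-fold (6.95 to 21.7). Because parental reads of 0 leave ratios open, the medians of these 3 lists are also given with such members at their bound: 5.07 and 0.93 for chromosome 19, 2.47 and 1.35 for DLK1-DIO3, and 3.54 and 1.97 for the fibroblast markers (4.09 and 1.95 with the identical pair counted once). Among random lists matched on abundance these medians lay at percentiles 78.7, 91.7 and 97.4 (98.2 with the pair counted once), and the 5 DLK1-DIO3 members with at least 100 reads lay at 49.0.

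Lower lists included the blood cell markers, with 4 of 5 lower and a median log2 ratio of -4.45, among them the erythroid miR-486-5p (27.1-fold, 20.3 to 36.7), the lymphocyte miR-150-5p (26.7-fold, 6.35 to 239) and the leukocyte miR-142-5p (10.3-fold, 5.58 to 20.4). The serum carry-over markers, which share miR-451a and miR-486-5p with that list, had 3 of 4 lower, or 2 under TMM. The neural markers had 4 of 5 lower, or 3 under TMM, among them miR-124-3p with 18 and 0 reads, at least 18.9-fold. Both measured arms of the endothelial miR-126 were lower, miR-126-3p by 15.1-fold (5.65 to 50.7).

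Of 305 miRNAs with at least 10 reads in either HCT15 library, 98 were at least 2-fold higher in spheres, 86 at least 2-fold lower and 121 within 2-fold, and 71 of the higher and 84 of the lower had counting intervals that exclude 1. TMM scaling moved the median log2 ratio by 0.61 and gave 123 higher and 51 lower, and DESeq2 size factors moved it by 0.53 and gave 120 and 56. Of the miRNAs named by the fixed rule, TMM took 12 of the 40 lower and 0 of the 44 higher to within 2-fold, and 6 others became at least 2-fold higher. With sphere reads thinned to the parental total, 60 were higher and 81 lower, and without the chromosome 19, DLK1-DIO3 and fibroblast lists, 58 were higher and 86 lower.

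The same question was asked of HCT29. The sphere exosomes of this line carried far more miR-375, which is abundant in secretory cells of gut and pancreas: 45016 RPM against 994, which is 45.3-fold higher (37.6 to 55.1). miR-125a-5p was 9.51-fold higher (7.92 to 11.5) and miR-215-5p, a miRNA of intestinal epithelium linked to p53, 4.54-fold higher (3.28 to 6.46). The miR-17-92 members miR-20a-5p and miR-17-5p were 35.4-fold (21.6 to 61.6) and 16.3-fold (11.4 to 23.6) lower. miR-200a-3p was 11.9-fold lower (10.4 to 13.7), and miR-21-5p was 4.03-fold lower (3.89 to 4.17), with a log2 ratio of -2.01 that became -0.84, within 2-fold, under TMM and -1.12 under DESeq2 factors.

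In the miR-17-92 clusters 8 of 11 measured members were lower and 1 higher, the latter with an interval that includes 1. The median log2 ratio was -2.64, at the lowest percentile of the lists in HCT29, 0.03 among random lists matched on abundance. Under TMM scaling 6 were lower and 3 higher, and the median was -1.52. The summed RPM of this list was 1.25 times the parental value, and its most abundant member, miR-92a-3p, was 1.77-fold higher. The miR-200 list had 6 of 8 lower and 0 higher, with 4 lower under TMM scaling, and miR-141-3p was 3.16-fold lower (2.91 to 3.43), or within 2-fold under TMM. Both miR-29 members were lower, miR-29a-3p by 4.85-fold (3.64 to 6.45) and miR-29b-3p, with 20 and 0 reads, by at least 32.0-fold. The miR-15 and miR-16 list had 3 of 3 lower, or 2 under TMM scaling, with miR-15a-5p 5.12-fold lower (2.37 to 11.1). In the miR-30 list 5 of 7 were lower, among them miR-30b-5p (12.6-fold, 9.97 to 16), and under TMM scaling 1 was lower and the list's median log2 ratio of -1.10 became 0.07. In the miR-23-27-24 clusters 3 of 6 were lower and 0 higher, which became 1 and 1, and their median of -0.92 became 0.25. In the colorectal cancer-raised list 6 of 11 were lower and 2 higher, miR-182-5p by 2.22-fold (2.12 to 2.32), and under the same scaling 3 were lower and 3 higher and the median of -1.20 became -0.03. The miR-10 list had miR-10b-5p 8.11-fold lower (7.04 to 9.35) and the other measured members within 2-fold, which became 2 higher under TMM.

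miR-146a-5p was also higher in HCT29 spheres, at 132 RPM against 45.2 (2.92-fold, 1.19 to 9.27), on 5 parental reads. The blood cell markers had 3 of 3 lower, with miR-486-5p 4.46-fold (3.57 to 5.57) and miR-142-5p 7.46-fold (3.01 to 19.5) lower, but 1 of 3 was lower under TMM scaling (median -0.99) and 2 of 3 under DESeq2 factors (-1.27). The fibroblast and smooth muscle markers had 3 of 3 lower, or 2 of 2 (median -3.51) with the identical miR-199a-3p and miR-199b-3p counted once, with miR-199a-3p 19.9-fold lower (8.52 to 53.7). Entries that overlap other abundant RNAs, such as ribosomal and transfer RNA, had 7 of 10 higher and 2 lower, among them miR-7704 at 8.46-fold (3.57 to 26.3). Of these 7, 3 had intervals that exclude 1, the median of 1.81 was 0.85 with counts of 0 at their bound, and the summed RPM was 1.15 times the parental value (0.947 to 1.40). The chromosome 19 cluster, the DLK1-DIO3 cluster and the pluripotent stem cell miRNAs had 0 members with at least 10 reads in an HCT29 library.

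Of 224 miRNAs with at least 10 reads in either HCT29 library, 52 were at least 2-fold higher, 81 at least 2-fold lower and 91 within 2-fold, and 26 of the higher and 73 of the lower had intervals that exclude 1. TMM scaling moved the median log2 ratio by 1.15 and gave 94 higher and 36 lower, and DESeq2 size factors moved it by 0.87 and gave 85 and 47, so the balance of higher and lower in this line depends on the scaling. Of the miRNAs named by the fixed rule, TMM took 14 of the 36 lower and 0 of the 20 higher to within 2-fold, and 16 others became at least 2-fold higher. With sphere reads thinned to the parental total, 23 were higher and 71 lower.

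**Figure D2:**
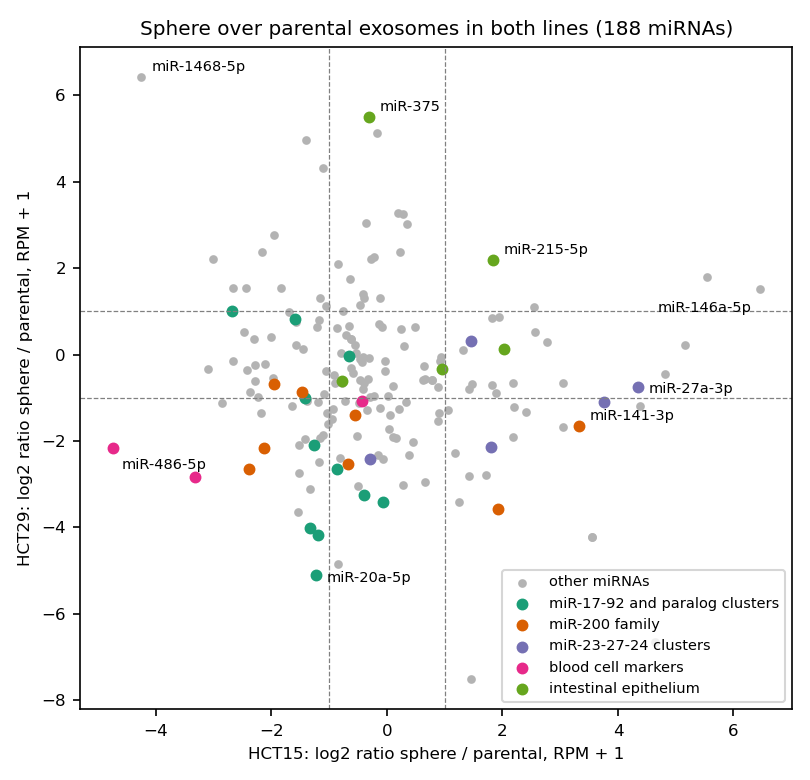
Log2 sphere over parental ratio of 188 miRNAs measured in both lines, HCT15 on the horizontal and HCT29 on the vertical axis, each point 1 miRNA, colours marking 5 lists and dashed lines 2-fold. 4 miRNAs lie in the higher corner of both lines, 25 in the lower corner and 30 in the opposite corners.

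The lines were set side by side to ask which miRNAs differed alike in the spheres of both, and few were higher in each. 4 of the 188 miRNAs measured in both were at least 2-fold higher in both: miR-146a-5p, miR-215-5p, miR-33b-5p and the p53 target miR-34a-5p. Of these, miR-146a-5p and miR-215-5p had intervals that exclude 1 in both lines, and the lists would share 6.47 if drawn independently. With such intervals required, as the plan had it for this count, 2 were higher in both, against 4.28 for independent lists, and 25 lower, against 21.3. At least 2-fold lower in both were 25, against 23.6 for independent lists, among them miR-486-5p, miR-142-5p and miR-30b-5p, of which TMM scaling kept miR-142-5p in both lines. Opposite ratios of at least 2-fold were seen for 30, against 25.2, among them miR-141-3p, miR-24-3p and miR-199a-3p, each higher in HCT15 spheres and lower in HCT29 spheres, although under TMM scaling the HCT29 log2 ratio of miR-24-3p turned to 0.0625 and that of miR-141-3p, at -0.49, came within 2-fold. Across these 188 miRNAs the log2 ratios of the lines had a Pearson r of -0.14 (bootstrap 95% interval -0.30 to 0.02) and a Spearman rho of -0.09, and miRNAs are not independent replicates. TMM scaling gave 14 higher and 3 lower in both lines, against 19.4 and 4.94 for independent lists, and DESeq2 size factors gave 13 and 5, against 16.5 and 7.55.

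With the lines as the replicates, limma on log2(RPM + 1) with a term for the line found 0 of 222 miRNAs past a Benjamini-Hochberg adjusted p of 0.05 in either direction, and 12 had an unadjusted p under 0.05. miR-146a-5p came first, with a mean log2 ratio of 3.99 (SE 1.29), higher in 2 of 2 lines, and an adjusted p of 0.488. Over the alternatives the smallest adjusted p ranged from 0.0245 to 0.996: edgeR and limma voom also gave 0, with 3 and 8 at an unadjusted p under 0.05, while DESeq2 gave 1 higher (miR-146a-5p, adjusted p 0.0473), as did limma on TMM-scaled values (miR-146a-5p, adjusted p 0.0245). Without a filter and with a pseudocount of 0.1, limma gave 1 lower (miR-451a, adjusted p 0.0472). Adjusted over the list alone by Benjamini-Hochberg on the limma p, miR-146a-5p passed within the miR-146 list of 2 tested members (adjusted p 0.0044). Of the 3 tested blood cell markers, miR-142-5p and miR-486-5p passed (smallest adjusted p 0.0273). Over all miRNAs 0 of these passed, and the adjustment over a list alone is not corrected for the number of lists. miR-486-5p also passed within the serum carry-over list alone. The hairpin of miR-146a lies on chromosome 5 (GRCh38) from 160485352 to 160485450, in an exon of the noncoding RNA gene MIR3142HG.

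**Figure D3:**
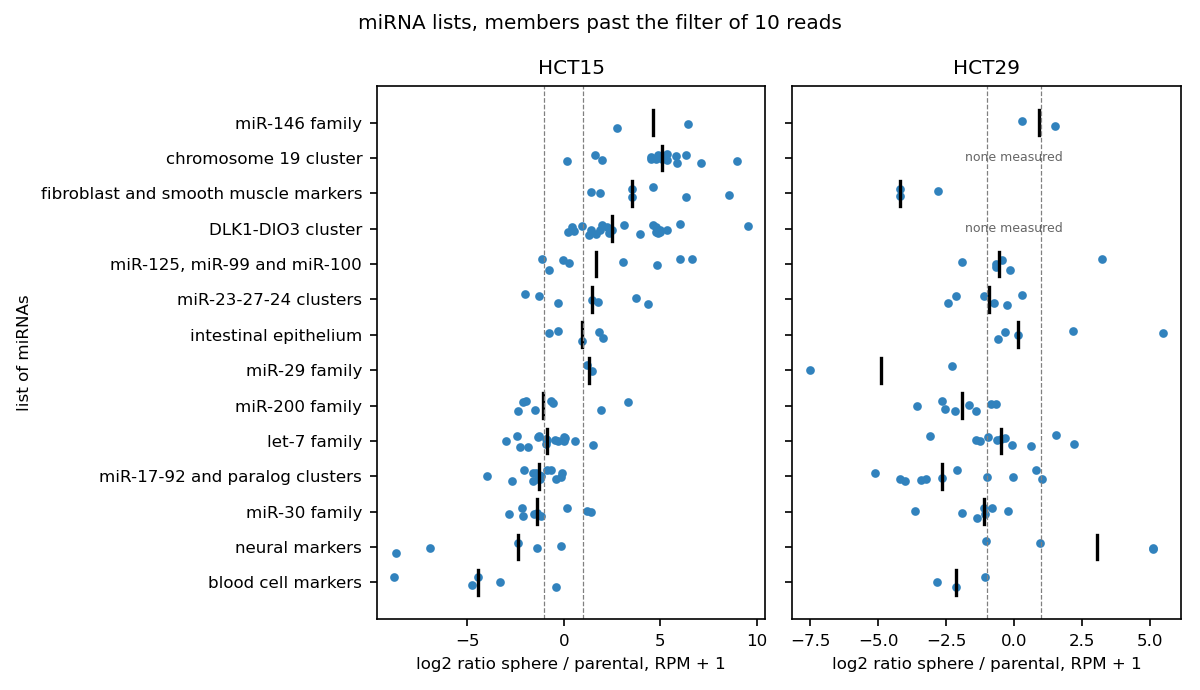
Log2 sphere over parental ratios of the measured members of 14 of the fixed miRNA lists in HCT15 and HCT29, on RPM + 1, each point 1 miRNA, each bar the list's median and dashed lines at 2-fold. The miR-146 list has medians of 4.61 and 0.91, and the miR-17-92 list has medians of -1.27 and -2.64.

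The lines themselves were compared over both cultures, to place the sphere ratios against the difference between the lines. HCT29 exosomes had far less of the measured members of the pluripotent stem cell list, which are transcribed together on chromosome 19 and are typical of embryonic stem cells. The miR-302 and miR-367 members of that list fell short of the filter in every library. miR-371a-5p had 879 and 1541 reads in HCT15 parental and sphere and 0 in both HCT29 libraries. On the floor of 3 reads it was at least 221-fold and at least 591-fold lower, with exact lower limits of 179 and 480. miR-373-3p was at least 83.0-fold and at least 243-fold lower (exact limits 67.1 and 197), and miR-372-3p at least 48.0-fold and at least 71.0-fold (38.7 and 57.2). HCT29 exosomes had far more of the intestinal miR-192-5p, by 60.7-fold in parental (52.0 to 71.2) and 16.3-fold in sphere exosomes (15.6 to 17.1), and more of miR-99b-5p, by 11.1-fold and 10.2-fold.

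limma on the line term, with Benjamini-Hochberg adjustment, found 8 miRNAs higher and 20 lower in HCT29 out of 222, each difference a mean over 2 libraries per line. Those libraries are 1 parental and 1 sphere preparation, which stand as replicates of the line although no preparation was repeated. Of the pluripotent list 4 of 4 fell below HCT15, with an adjusted p for miR-371a-5p of 4.95e-15 by limma, 0.00042 by edgeR and 1.75e-08 by DESeq2. The limma value rests on a spread pooled over miRNAs and on HCT29 counts of 0 with the added 1 RPM. With a pseudocount of 0.1 the smallest limma adjusted p, also for miR-371a-5p, was 0.00017. No member of the pluripotent list or of the DLK1-DIO3 cluster reached the filter's minimum of reads in an HCT29 library. Each tested member therefore entered through both HCT15 libraries, and the filter favoured lower calls in these lists. Of the DLK1-DIO3 cluster 6 of 6 were lower: miR-411-5p, miR-381-3p, miR-410-3p, miR-136-3p, miR-409-3p and miR-127-3p. In parental exosomes these 6 were 5.28-fold (miR-381-3p, 1.21 to 47.9) to 9.43-fold (miR-136-3p, 2.35 to 82.2) lower, on 2 to 6 HCT29 reads each. In sphere exosomes they were 41.9-fold (miR-409-3p, 17.6 to 131) to 473-fold (miR-411-5p, 84.4 to 1.87e+04) lower where HCT29 had reads, so the mean leans on the sphere libraries. The intestinal list had 3 of 5 higher, miR-192-5p (log2 difference 4.98), miR-194-5p (4.01) and miR-215-5p (3.78), of which edgeR passed miR-192-5p alone (edgeR adjusted p 0.0699 for miR-194-5p and 0.0854 for miR-215-5p) and DESeq2 all 3. miR-146a-5p was lower in HCT29 (log2 difference -4.47, limma adjusted p 0.0108), as were miR-10b-5p (-4.23), miR-125b-5p, miR-100-5p, miR-320c, miR-320d, miR-155-5p, miR-152-3p and miR-132-3p. None of these 9 passed edgeR (adjusted p 0.188 for miR-146a-5p and 0.150 for miR-10b-5p), and DESeq2 passed miR-146a-5p and miR-10b-5p. The differences were also larger between the sphere libraries for miR-146a-5p and miR-100-5p, which were far higher in HCT15 spheres, and for miR-10b-5p, which was lower in HCT29 spheres: miR-146a-5p was 4.08-fold lower in parental (1.55 to 13.6) and 123-fold in sphere exosomes (97.2 to 158), miR-100-5p 1.99-fold (1.05 to 3.99) and 77.1-fold (58.1 to 104), and miR-10b-5p 6.02-fold (5.50 to 6.60) and 58.9-fold (52.6 to 66). Adjusted over the list alone, without correction for the number of lists, the counts were the same for these lists except the miR-148 and miR-152 list, which went from 1 to 3. The miR-30 list, with 0 over all miRNAs, had 1 (miR-30a-5p), and the entries overlapping other RNAs, also with 0, had 2 (miR-1290 and miR-7704).

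edgeR with TMM scaling gave 5 higher and 5 lower, with 0 of the DLK1-DIO3 members (smallest edgeR adjusted p 0.0653), DESeq2 gave 9 and 8, with miR-411-5p and miR-381-3p among the lower, and limma voom gave 6 and 5. DESeq2 gave no adjusted p for 35 of the 222 miRNAs, among them miR-371a-3p of the pluripotent list. With the culture term left out, each library mattered: limma gave 0 higher and 6 lower without HCT15 parental, 0 and 6 without HCT15 sphere, 3 and 15 without HCT29 parental, and 2 and 10 without HCT29 sphere, against 2 and 5 with all 4 libraries and no culture term.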

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

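Except for the test of GC trends, the tests in this part were chosen only after the result was seen. 24 miRNAs had sphere over parental ratios of at least 2-fold in opposite directions in the lines, with counting intervals that exclude 1 in both. The 17 of them that the fixed naming rule also picked are given here, and the difference between the lines was not tested, since each ratio rests on 1 library per culture. The values are the HCT29 log2 ratio minus the HCT15 log2 ratio.

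Higher in HCT15 spheres and lower in HCT29 spheres were miR-141-3p (-4.99) and miR-200a-3p (-5.50) of the miR-200 family, miR-183-5p (-3.41) and miR-96-5p (-4.09) of 1 cluster, miR-23a-3p (-3.94) and miR-24-3p (-4.86), miR-29a-3p (-3.46) and miR-29b-3p (-8.96), miR-21-3p (-4.49), and miR-199a-3p and miR-199b-3p (-7.76 each, identical values). Under TMM scaling the HCT29 log2 ratio of miR-24-3p turned to 0.0625, and those of miR-183-5p (-0.03), miR-141-3p (-0.49), miR-96-5p (-0.76) and miR-23a-3p (-0.97) came within 2-fold. Lower in HCT15 spheres and higher in HCT29 spheres were miR-1468-5p (10.68), miR-3615 (4.73), miR-1260a (4.21) and miR-1260b (3.99), let-7d-3p (3.39) and miR-423-5p (2.18), whose HCT15 log2 ratio of -1.06 became -0.45 under TMM scaling. The values for miR-1468-5p and miR-29b-3p rest on a count of 0 in HCT29 and depend on the added 1 RPM, so they are not bounds, and miR-3615 rests on 1 read in HCT29 parental.

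The chromosome 19 and DLK1-DIO3 clusters were 29.8-fold (14.4 to 74.3) and 3.14-fold (2.73 to 3.63) higher in summed RPM in the HCT15 sphere library than in the parental one, with medians at percentiles 78.7 and 91.7 of matched random lists. At the parental total the sphere library would hold 208.3 chromosome 19 reads, against an upper limit of 14.4 in the parental library, and 669.3 DLK1-DIO3 reads against 243.6. These values restate the RPM folds, which already scale for depth and whose intervals exclude 1. They show sums beyond depth and counting error and are no separate test. A library taken from the other line is argued against, since the HCT15 sphere library held 2422 reads of the pluripotent stem cell list, of which both HCT29 libraries had 0. That line also had few reads of these clusters to supply: 2 and 0 of chromosome 19 and 19 and 11 of DLK1-DIO3, in HCT29 parental and sphere. RNA from fibroblast-like cells stays open: the fibroblast list, whose 5 listed hairpins overlap neither cluster, lay at percentile 97.4, or 98.2 with the identical miR-199a-3p and miR-199b-3p counted once (miR-143-3p 2.68-fold and miR-199a-3p 11.8-fold higher), but miR-145-5p had 1 and 4 reads, and the lower limit of its ratio, 0.126, excludes nothing. A change of the HCT15 cells in sphere culture, which the design names, may also be the source and was not tested apart from the medium.

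Blood cell miRNAs were lower in both sphere libraries on the deposited scale, by 6.28-fold (5.53 to 7.15) in HCT15 and 4.36-fold (3.56 to 5.33) in HCT29 in summed RPM, but in HCT29 TMM scaling left 1 of 3 members lower (median -0.99) and DESeq2 factors 2 of 3 (-1.27). Serum carried over in the parental medium may account for the difference and cannot be told apart from the culture, because the medium changed with it: the list lay at percentiles 0.23 and 7.98, while the labels call the medium used to collect parental exosomes exosome-depleted. The serum carry-over list, which also holds miR-423, was 1.95-fold lower (1.84 to 2.07) in summed RPM in HCT15 spheres and 1.22-fold higher (1.09 to 1.36) in HCT29 spheres. The most abundant blood cell marker in HCT15 parental, miR-486-5p, was 3109 and 115 RPM in HCT15 parental and sphere, while the liver miRNA miR-122-5p, another serum marker, had 0, 0, 1 and 0 reads in HCT15 parental, HCT15 sphere, HCT29 parental and HCT29 sphere. A change of these miRNAs in the cells themselves stays open as untested.

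The sphere ratios of the lines had no positive correlation, with a Pearson r of -0.14. Opposite GC trends are argued against as the whole cause: after a linear GC trend was removed in each line, r was -0.1006 (-0.27 to 0.08) over 188 miRNAs. Among 83 miRNAs with at least 30 reads in all 4 libraries, r was -0.0358 (-0.19 to 0.10), so counting noise is argued against for these. The bound for both tests was an upper end of the interval under 0.3. The filter of 30 reads leaves out miRNAs with few reads in any library, such as miR-146a-5p with 27 and 5 parental reads, which narrows the range of ratios. With 100 reads required in 1 library of each line instead, r was -0.06 (-0.24 to 0.10) over 76 miRNAs. For miRNAs with few reads, counting noise stays open. A difference between the lines in how they respond to sphere culture, or between single preparations, is consistent with these values, and 1 library per group does not separate them.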

How the results depend on the processing

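The settings with thinning, TMM-scaled limma, edgeR with the deposited totals, left-out lists, left-out libraries and identical miR-199 values counted once were chosen only after the result was seen. So was the interval as a criterion on RPM + 1 within a line, although the plan's first form held it. Reversed here means that a ratio of at least 2-fold changed sign. 3 named ratios did, in HCT29 under TMM scaling: miR-24-3p to 0.0625, miR-148b-5p to 0.0218 and miR-378c to 0.0759 log2. 13 named ratios within 2-fold in HCT29, such as miR-10a-5p (-0.06 to 1.11), also changed sign under TMM, and 12 in HCT15. Of the named ratios not reversed 2057 stayed within their interval and 233 moved, and of the list medians 77 stayed and 86 moved. Counts are given as higher, then lower; HCT15 and HCT29 are the ratios within each line, and a count left out stayed within 1.5 times the main one. TMM gave 51 lower in HCT15, 94 and 36 in HCT29, and 14 and 3 in both lines, and DESeq2 factors gave 56 lower, 85 and 47, and 13 and 5. No filter gave 390 and 227, 176 and 236, and 48 and 62, the last pair against 37.1 and 60.9 for independent lists. A filter of 100 reads gave 36 and 29, 18 and 31, and 0 and 8, the last pair against 2.46 and 8.84. With these filters fewer or more miRNAs enter by construction. A 4-fold threshold gave 41 lower in HCT15, 31 and 41 in HCT29, and 0 and 4 in both. A prior count of 5 reads gave 2 higher in both lines. Opposite ratios, 30 in the main setting, were 6 at the 4-fold threshold, 13 with the filter of 100 reads and 94 without filter. Independent lists would give 6.21, 9.74 and 96.6. The interval criterion gave 26 higher in HCT29 and 2 in both, thinning gave 60 higher in HCT15, 23 in HCT29 and 2 in both, and the left-out lists gave 58 higher in HCT15. For culture over both lines, DESeq2 gave 1 higher, limma on TMM-scaled values 1 higher, and a pseudocount of 0.1 without filter 1 lower. For HCT29 against HCT15, a pseudocount of 0.1 gave 2 and 3, no filter 5 and 12, 100 reads 4 and 5, a pseudocount of 10 without filter 4 and 8, no culture term 2 and 5, edgeR with TMM 5 and 5, with DESeq2 factors 3 and 4 and with the deposited totals 2 and 5, DESeq2 8 lower, and limma voom 5 lower. Leaving out each library gave 0 to 3 higher and 6 to 15 lower. Apart from the numbers of miRNAs entering, the cause was not tested. The correlation between the lines stayed between -0.18 and -0.01 under every setting. Sums over repeated names and another normalized column gave no value, since no name is repeated and the tables hold RPM alone. With each library left out and both terms kept, no residual degree of freedom remains, so those fits dropped the other term and assume that a lone library varies like the rest. Depth limits the parental libraries most, where 1 read is 6.82 and 9.04 RPM.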

Other observations

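The miRNA lists and the TMM and DESeq2 scalings in this part were fixed before the data were examined. Except for the GC trends, the tests, such as that of hairpin arms, were chosen only after the result was seen. Families not described above are given here for HCT15 spheres with their median log2 ratio. The miR-10 list had 3 of 3 within 2-fold (0.27), with miR-10a-5p 1.92-fold higher (1.90 to 1.95), but 1 of 3 higher under TMM (median 0.88) and under DESeq2 factors (0.80), and the miR-221 and miR-222 list, linked to proliferation, had 4 of 4 within 2-fold (-0.28, which became 0.33 under TMM scaling). The miR-181 list had 2 of 7 lower (-0.50, which became 0.10 with 1 higher and 0 lower), and the miR-148 and miR-152 list 1 of 5 lower (0.21, which became 0.82 with 2 higher). The miR-378 list had 1 of 3 lower (-0.73, which became -0.12 with 1 higher and 1 lower under TMM scaling), its most abundant member miR-378a-3p. In summed RPM the list was 4.35-fold lower (3.97 to 4.77). The colorectal cancer-raised list had 4 of 13 higher and 0 lower (-0.12, which became 0.48 with 5 higher). The miR-29 list, which targets collagen mRNAs, had 2 of 2 higher (1.32) and was 2.24-fold higher (1.89 to 2.66) in summed RPM, and the miR-15 and miR-16 list 3 of 7 higher (0.38). The hypoxia miRNA had its minor arm miR-210-5p 56.6-fold lower (8.94 to 2.36e+03, on 1 sphere read) and miR-210-3p at 1.07 times the parental level (0.846 to 1.37). The pluripotent list had 1 of 4 lower, miR-372-3p by 3.25-fold (2.64 to 4.0), and 0 higher. The entries overlapping other RNAs had 2 of 10 higher and 4 lower (-0.63), or 4 and 3 under TMM scaling (-0.02), and muscle markers had 1 read in HCT15 sphere and 0 in the other libraries.

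In HCT29 the medians of many lists lay close enough to 0 that TMM scaling turned them. The let-7 list had 2 of 11 higher and 3 lower (-0.48, which became 0.69), the miR-125, miR-99 and miR-100 list 1 higher and 1 lower of 6 (-0.55, 0.59), the miR-10 list 1 of 3 lower (-0.06, 1.11), the miR-181 list 2 of 6 lower (-0.38, 0.78), the miR-148 and miR-152 list 2 of 3 lower (-1.12, 0.02), the miR-221 and miR-222 list 1 of 3 lower (-0.80, 0.34), the miR-378 list 1 of 3 lower (-0.97, 0.19) and the endothelial list 0 of 1 past 2-fold (-0.87, 0.30). Under TMM the higher and lower members of these lists, in the same order, were 4 and 1, 2 and 0, 2 and 1, 2 and 1, 0 and 0, 1 and 1, 0 and 0, and 0 and 0. The intestinal list had 2 of 5 higher, miR-375 and miR-215-5p, and 0 lower (0.14), with 3 higher under TMM scaling. The miR-183-96-182 cluster had 1 of 3 higher and 2 lower (-1.20), which became 1 higher and 0 lower under TMM scaling (-0.03), and its summed RPM was 1.36 times the parental value (1.32 to 1.41). The miR-320 list had 3 of 3 within 2-fold (0.86), with 2 higher under TMM, and the miR-34 list had 1 of 1 higher, with an interval that includes 1. The hypoxia miRNA miR-210-3p was 3.80-fold lower (2.64 to 5.45), with a log2 ratio of -0.75 under TMM. The neural list had 2 of 4 higher and 1 lower (median 3.04, or 0.32 with counts of 0 at their bound), and 3 higher and 0 lower under TMM scaling. None of its higher members had an interval that excludes 1, and its summed RPM was 0.775 times the parental value (0.541 to 1.13). The serum carry-over list split, with miR-423-5p 2.18-fold higher (1.84 to 2.60) and miR-486-5p 4.46-fold lower (3.57 to 5.57), and had 2 higher and 0 lower under TMM scaling.

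The sphere ratios also followed the GC content of the hairpin arm that holds the miRNA, in opposite directions in the lines. In HCT15 the Spearman rho across 305 miRNAs was -0.208 (two-sided permutation p 0.00049, Benjamini-Hochberg adjusted 0.00049), and in HCT29 across 224 miRNAs it was 0.324 (p 1e-05, the smallest that 100000 permutations can give, adjusted 2e-05). miRNAs are not independent replicates in these tests. In 4 bins of GC content, from lowest to highest, the median log2 ratios were 0.54, 0.37, -0.63 and -0.45 in HCT15 and -1.07, -0.80, 0.26 and 0.25 in HCT29. Among miRNAs with at least 30 reads in both libraries of the line, rho was -0.167 (119 miRNAs) and 0.190 (96 miRNAs).

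Some hairpins had arms that moved apart, which may reflect a preference for 1 arm in sphere exosomes, and this was tested as a hypothesis. The median of the 3p minus 5p log2 ratio was 0.41 over 59 hairpins in HCT15 and -0.2119 over 34 hairpins in HCT29. The test was on the mean difference. That mean was 0.48 in HCT15 (two-sided sign-flip permutation p 0.137, adjusted 0.274) and -0.19 in HCT29 (p 0.681 by the same test, adjusted 0.681). Medians and means had opposite signs in the lines, and neither test passed. Arms with ratios of at least 2-fold in opposite directions, each with an interval that excludes 1, were seen for 4 hairpins in HCT15 (miR-1307, miR-200a, miR-27a and miR-361) and 2 in HCT29 (let-7d and miR-454), and were named after their values were seen.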
